A study of Arabidopsis thaliana with 3 samples.

How the data were processed

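Nuclear RNA from whole 12-day-old seedlings was depleted of ribosomal RNA, ligated to a 3′ linker, reverse transcribed with strand switching, amplified by PCR and sequenced on nanopore flow cells, per the labels' protocols. There was 1 library each for wild type, spt16 and ssrp1, and the group of each came from its label. Reads were aligned with minimap2, per the submitters' processing notes, which give no version. The genome build, the annotation and the program that assigned reads to genes are not given in the sources used here.

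The authors deposited 1 table per library with 1 row per aligned read and gene. Each row holds the positions of the read and the gene, the distances of the read ends from the annotated gene ends, the introns spanned and unspliced, a read class and a tail length in nt, per the file headers. These values are not normalised. Every read the authors classed as polyadenylated had a tail of at least 15 nt. All rows had read and gene on the same strand, so antisense reads were not analysed here. Reads listed in more than 1 row made up 1.23%, 0.855% and 0.741% of rows in wild type, spt16 and ssrp1. The read counts, shares and log2 ratios below were computed from the deposited rows.

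Of 27840 genes in the files, 27566 were nuclear, and each of these matched the reference name table (TAIR10.1 names), where 23486 are protein-coding. Of the matched genes 81.5% had the same start and end in both, so coordinates are given as the files give them and only names were taken from the table. Gene symbols in the fixed lists were written before the data were examined.

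Elongating reads are the authors' classes of reads without a tail, whether or not the 5′ part was lost, and exclude splicing intermediates and reads with a poorly mapped 3′ end. Introns were counted only where a read fully spanned them, because the deposited intron numbers also count an intron in which a read begins, always as unspliced. Exon and intron borders were rebuilt from the rows of each gene. Distances from introns to read 3′ ends were therefore missing for introns whose borders could not be rebuilt, while 14315 of 20585 genes with introns had complete models. Three-prime ends were counted in protein-coding genes of at least 1000 nt, in the first 300 nt or past the annotated end. Five-prime ends of polyadenylated reads were called internal from 200 nt inside the gene.

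Gene abundance was expressed as RPM, reads scaled to the nuclear gene reads of each library. Log2 ratios used a pseudocount of 0.5, and intervals were exact conditional binomial intervals. Protein-coding genes with at least 50 reads over the 2 libraries compared were tested, 13219 for spt16 and 13278 for ssrp1, and a gene was listed as higher or lower when its whole 95% interval lay beyond 2-fold. No p-value across genes was computed. Printed folds are relative to the median gene. Shares have exact Clopper-Pearson intervals, differences of shares Newcombe intervals, counts exact Poisson intervals, and median tails an interval from 1000 bootstrap draws of the median over reads. A count of 0 was read as an upper limit of 3 counts for folds and shares. PCR copies were not marked by molecular identifiers, so reads are not all independent molecules and intervals cover counting error only. Introns of 1 read were counted as separate observations, which makes intervals of unspliced shares too narrow. As an alternative they were given the number of independent observations they hold if all introns of 1 read share 1 state. The wild type library was the deepest, and a gene with few reads has a wide interval whatever its ratio.

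The median log2 ratio of each gene list was placed among 10000 random lists of equal size matched on mean abundance in 20 bins. The lists were FACT subunits, H2A.Z and its exchange complexes, transcript elongation factors, core histones, flowering-time regulators, anthocyanin and flavonoid genes, heat-shock response, DNA damage response, pathogen defence, jasmonate response, nuclear photosynthesis, morning-phased and evening-phased clock genes, root markers, dividing cell markers and cytosolic ribosomal proteins. The last list held only the 7 genes so named in the reference name table. A member of a list was called higher or lower beyond counting error when its interval, relative to the median gene, excluded 0. For shared control reads, 100 sets of unchanged libraries were simulated from the pooled abundances, for the correlation and for the overlap of listed genes.

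Named genes followed a rule fixed before the data were examined: for the spt16-labelled library and for ssrp1 the 10 highest and 10 lowest genes by the interval bound nearest 0, both FACT genes, up to 4 members of each list with at least 20 reads and the widest ratio, FLC and its list, and up to 5 genes per read measure, from genes with at least 50 such reads in each library, by the interval of the difference. Not every gene the rule took is named. The ranking used the fixed scaling, and the printed values are relative to the median gene.

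Genes with stacked reads were defined after seeing the data, as 223 genes in which, on average over the libraries, at least 20% of reads without a tail shared 1 pair of end positions in bins of 20 nt, with at least 300 such reads in all. They were left out only as an alternative. The limit on ssrp1 molecules in the spt16-labelled library was also set after seeing the data, from the lower 95% bound of the ratio of SSRP1 reads reaching the last 300 nt. The ratio intervals were tested on simulated data with 200 changed genes: of genes lowered to 0.25 of their level, 71.1% were listed in the spt16 simulation over 13386 genes and 78.6% in the ssrp1 simulation over 13383 genes, of genes raised 4-fold 100% were listed in both, and no unchanged gene was. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the genes pooled, tail and position limits, read class, scaling, read minimum, pseudocount and depth. Organellar reads entered no gene-level comparison.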

Results

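Nuclear RNA of 12-day-old Arabidopsis thaliana seedlings was profiled by FLEP-seq2, a nanopore method that ligates a linker to RNA 3′ ends and reads long cDNA molecules, so that each read carries its 3′ end, the splicing state of its introns and its poly(A) tail. One library was made from wild type (the Columbia accession), and 2 others carry the labels of an spt16 and an ssrp1 mutant. SPT16 and SSRP1 are the subunits of FACT, a histone chaperone that travels with RNA polymerase II. Each mutant label was compared with wild type here to ask how transcription differs, while the labels do not state the allele. The series title sets the comparison beside the histone variant H2A.Z. The files listed 3577731 aligned reads for wild type, 2160689 for spt16 and 2063580 for ssrp1, of which 3115189, 1772079 and 1755964 lay in nuclear genes. Because there was 1 library per genotype, none of the differences has a replicate check. All intervals are 95% intervals that cover counting error only, and they compare libraries, not genotypes.

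The targeted genes were examined first. SSRP1 (AT3G28730, chromosome 3, positions 10784888 to 10788729, plus strand, 15 introns) had 72 reads in the ssrp1 library, and none of them reached the last 300 nt of the annotated gene, which allows a share of up to 4.17% (3 of 72). In wild type 33 of 78 reads (42.3%, interval 31.2 to 54.0%) ended there, and in the spt16 library 18 of 52 (34.6%, interval 21.97 to 49.1%). All 12 polyadenylated SSRP1 reads of the ssrp1 library stopped at least 300 nt before the annotated end, the farthest at -331 nt from it, while no polyadenylated read of wild type and 2 of 16 in the spt16 library did so. These 2, and 1 spt16 read without a tail, ended at the same nucleotide (-331) as 11 reads of the ssrp1 library, while none of the 78 wild type reads did. The 2 tailed reads also share their start, so these are only 2 distinct start positions, against 9 in ssrp1, and PCR copies were not marked. Untailed SSRP1 reads ended at shared positions in all 3 libraries, as at 3385 nt from the gene start, so the third read is weak evidence. Whether some ssrp1 molecules entered the spt16 sample stays open. Material equal to the sequenced wild type library, mixed with them, would hold at most 49.2% of them, by the 18 and 33 reads that reached the last 300 nt and the library sizes. Such a mixture would lower a gene at most 1.97-fold. GRP7 was 3.03-fold lower (2.85 to 3.23) in the spt16 library scaled to nuclear reads. Of the 24 genes called lower in both libraries below, 18 had their whole interval beyond that limit. A mixture with material equal to the wild type library is thus not the whole cause of the likeness described below. The limit does not cover wild type material that differed from that library, as in harvest time, and these genes were picked from the same data. SSRP1 abundance itself was not lower in the ssrp1 library, where its log2 ratio to wild type was 0.47 (interval -0.01 to 0.95) relative to the median gene.

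SPT16 (AT4G10710, chromosome 4, positions 6601903 to 6606357, minus strand, 1 intron) gave no such difference. Its abundance was 24.8 RPM (reads scaled to the nuclear gene reads of the library) in the library labelled spt16 (44 reads, interval 18.0 to 33.3), 23.4 in wild type (73 reads, 18.4 to 29.5) and 50.1 in ssrp1 (88 reads, 40.2 to 61.7). Reads starting within 200 nt of the annotated start made up 11.4% in the library labelled spt16 (interval 3.79 to 24.6%), 24.7% in wild type (15.3 to 36.1%) and 4.55% in ssrp1 (1.25 to 11.2%), so low 5′ coverage did not set the spt16 label apart. The labels do not state the allele, and the label of this library was left unchecked by its own gene, while a few of its SSRP1 reads carry the end seen in ssrp1. It is called the library labelled spt16, or the spt16-labelled library, from here on.

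**Figure D1:**
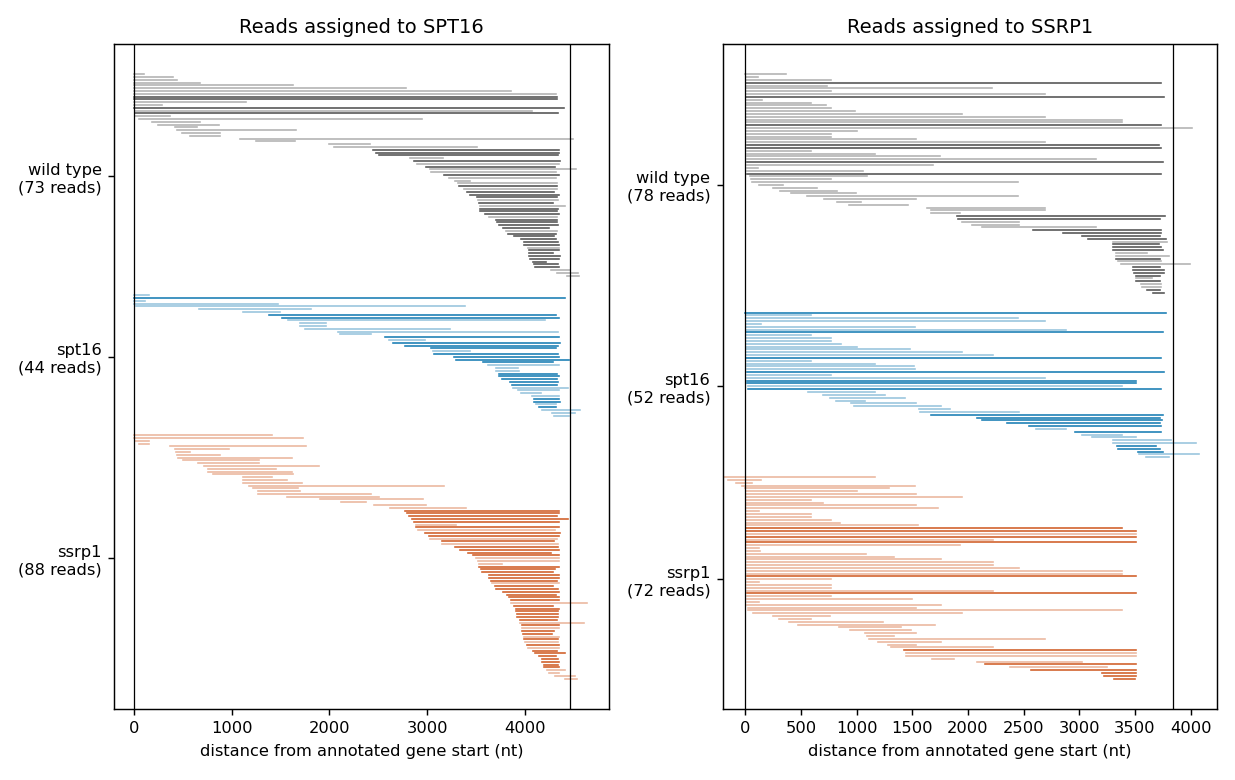
Each line is 1 aligned read of SPT16 (left) or SSRP1 (right), drawn from its 5′ to its 3′ end in nt from the annotated gene start; dark lines are polyadenylated reads, pale lines are reads without a tail, and vertical lines mark the annotated ends. In the ssrp1 library none of the 72 SSRP1 reads enters the last 300 nt of the gene, against 33 of 78 in wild type.

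The highest genes in the spt16-labelled library included RRTF1 and LOX4. The gene AT1G19210 was 91.2-fold higher than in wild type (interval 35.8 to 519; 212 against 3 reads), and RRTF1 (AT4G34410, also called ERF109, a transcription factor of the rapid wound and redox response) was 75.8-fold higher (29.7 to 431). The lipoxygenase gene LOX4 (AT1G72520), which acts in jasmonate synthesis, was 21.1-fold higher (15.4 to 30.4; 555 against 39 reads), CYP94B3 (AT3G48520), which oxidises jasmonoyl-isoleucine, was 21.4-fold higher (9.62 to 74.2), and the cell wall gene XTH18 (AT4G30280) was 10.9-fold higher (9.08 to 13.4). MYB15 (AT3G23250) was 11.3-fold, AT3G02840 30.8-fold, AT3G01830 30.7-fold, BPS3 (AT4G01360) 16.2-fold and AT2G24600 9.74-fold higher. The lowest genes included the seed storage proteins CRA1 (AT5G44120) and CRU3 (AT4G28520), with 71 and 58 reads in wild type and 0 in the spt16-labelled library, at least 15.8-fold and 12.9-fold lower against a floor of 3 counts per library. That limit leaves out the counting error of the wild type reads, and with it the 95% bounds were 12.5-fold and 10.1-fold.

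These folds are relative to the median gene, since the median log2 ratio over all tested protein-coding genes stood 0.23 above 0 in the spt16-labelled library and 0.24 above 0 in ssrp1 when libraries were scaled to nuclear gene reads. These medians were -0.0398 and 0.02 without genes with stacked reads, 0.47 and 0.50 with elongating reads and -0.00119 and 0.04 with polyadenylated reads. Under that fixed scaling, 345 of 13219 genes were higher and 21 lower in the spt16-labelled library with the whole interval beyond 2-fold. Relative to the median gene the numbers were 236 and 36. Simulated libraries with no difference but counting error gave 0.01 such genes on average. That value leaves out differences between plants and library preparations of 1 genotype. Against the 345 and 21, polyadenylated reads alone gave 85 higher and 19 lower. Elongating reads alone, whose median ratio was 0.47, gave 394 higher and 5 lower. Without genes with stacked reads the numbers were 225 and 33, with at least 200 reads 218 and 11, and with libraries thinned to the shallowest 13 were lower.

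The lists were fixed before the data were examined. Pathogen defence genes had a median log2 ratio of 1.404 relative to the median gene in the spt16-labelled library. That lay at the 100th percentile of 10000 random lists of matched abundance. Of the 16 genes listed 8 were measured, and 7 of 8 were higher beyond counting error. The read minimum counts reads of wild type and the library compared, so higher genes pass it more easily. In ssrp1 only 6 passed, so the 7 of 8 may rest partly on that minimum. With a minimum of 20 reads the median was 1.17 (percentile 100) in the spt16-labelled library. FRK1 (AT2G19190), a receptor kinase gene induced by bacterial flagellin, was 6.74-fold higher (4.15 to 12.0), and the transcription factor genes WRKY33 (AT2G38470), CBP60g (AT5G26920) and SARD1 (AT1G73805) were 4.04-fold, 3.42-fold and 3.12-fold higher. Jasmonate response genes had a median of 0.84 (percentile 99.9), with 6 of 7 measured members (of 15 listed) higher and 1 lower. LOX3 (AT1G17420) was 8.89-fold higher (6.72 to 12.1) and OPR3 (AT2G06050), an enzyme of jasmonate synthesis, 3.47-fold higher (2.83 to 4.29). In the ssrp1 library the defence list had a median of 0.55 (percentile 99.4; 4 of 6 members higher), but 0.18 (percentile 73.8) with elongating reads alone. The jasmonate list had 0.38 there (percentile 97.4, inside the central 95%; 2 of 7 higher), against 0.37 (percentile 98.2, outside it) with a minimum of 20 reads and 0.18 (percentile 78.3) with elongating reads. In ssrp1 LOX3 stood at 1.39-fold (0.931 to 2.07) and WRKY33 at 1.19-fold (0.968 to 1.47). The difference between these 2 libraries in the lists was not tested.

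The highest and lowest genes in the ssrp1 library included clock genes. LHY (AT1G01060), a morning-expressed repressor of the circadian clock, was 12.6-fold higher than in wild type (6.40 to 32.0; 71 against 8 reads), and its partner CCA1 (AT2G46830) was 4.89-fold higher (3.56 to 6.93). GRP7 (AT2G21660), an RNA-binding protein gene under clock control, was 8.24-fold lower (7.53 to 9.05; 502 against 6208 reads). The cold- and clock-regulated COR27 (AT5G42900) had 2 reads against 77, a ratio of 20.7-fold lower with an interval of 6.87 to 216. Genes outside the clock lists were SUS4 (AT3G43190, sucrose synthase, 11.9-fold higher, 5.47 to 36.4), ADH1 (AT1G77120, alcohol dehydrogenase, 5.41-fold higher, 3.14 to 10.3) and LSU1 (AT3G49580, induced by low sulphur, 6.12-fold higher, 4.18 to 9.41), along with AT1G75945 (6.23-fold), AT2G41250 (4.00-fold), AT5G41750 (4.23-fold), AT3G12320 (3.77-fold) and AT3G13857 (3.86-fold, stacked reads).

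Lower in ssrp1 were RbcX1 (AT4G04330, a chaperone of Rubisco assembly, 7.74-fold, 6.20 to 9.87), LCR69 (AT2G02100, 6.97-fold, 5.45 to 9.18), AT5G62360 (9.12-fold, 6.09 to 14.9) and AT2G30766 (18.5-fold, 6.13 to 194). AT1G07050 and AT3G02480 had 1 read each against 100 and 81 in wild type, and CRA1 and CRU3 had 2 and 1. All 4 of these, with COR27, GRP7 and RbcX1, were also among the 10 lowest in the spt16-labelled library, where GRP7 was 3.55-fold lower (3.33 to 3.78), RbcX1 3.12-fold (2.68 to 3.65), AT1G07050 14.9-fold (6.30 to 62.3), AT3G02480 15.5-fold (5.94 to 89.0) and COR27 14.7-fold (5.63 to 84.7). The remaining members of that group were the sugar transporter gene SWEET12 (AT5G23660, 4.66-fold lower, 3.03 to 7.80), AT1G47400 (7.03-fold, 2.86 to 29.9) and AT2G31141, whose reads piled up at a single position.

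In the ssrp1 library 95 of 13278 genes were higher and 38 lower beyond 2-fold under the fixed scaling. Relative to the median gene the split turned to 40 higher and 67 lower, so the balance of directions in ssrp1 rests on the scaling. Simulated equal libraries, which differ by counting error alone, gave 0.06 such genes on average. Against the 95 and 38, polyadenylated reads alone gave 13 higher and 33 lower, and elongating reads alone 90 and 9. A minimum of 200 reads gave 38 and 18, and leaving out genes with stacked reads 43 and 64.

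The 2 clock lists moved apart from each other in the spt16-labelled library and in ssrp1. All 7 evening-phased genes were lower beyond counting error in both, with list medians of -1.55 in the spt16-labelled library and -2.50 in ssrp1, each below all 10000 matched random lists, and -0.97 and -1.61 with elongating reads alone. LUX (AT3G46640), ELF4 (AT2G40080) and PRR5 (AT5G24470), which act in the evening part of the clock, were 3.39-fold, 3.72-fold and 2.94-fold lower in the spt16-labelled library and 7.65-fold, 7.04-fold and 5.65-fold lower in ssrp1. Morning-phased genes had medians of 0.83 (percentile 99.9; 4 of 6 members higher) and 1.54 (percentile 100; 6 of 7 higher and 1 lower). With elongating reads alone the former was 0.55 (percentile 95.9), inside the central 95% of random lists, and with polyadenylated reads the latter was 0.95. In the spt16-labelled library LHY was 5.04-fold, CCA1 3.38-fold and LNK2 (AT3G54500) 2.49-fold higher. The labels record no time of harvest.

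**Figure D2:**
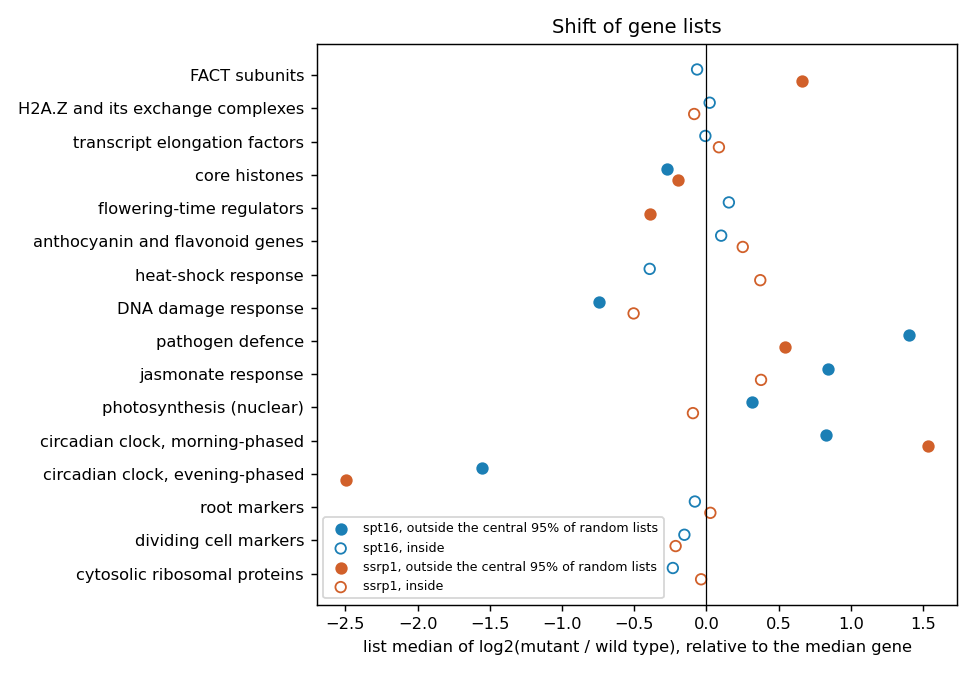
Points give the median over the measured genes of each list of the log2 ratio to wild type, relative to the median gene, for the spt16-labelled (blue) and ssrp1 (orange) libraries; filled points lie outside the central 95% of matched random lists. Evening-phased clock genes have the lowest medians, -1.55 and -2.50, and pathogen defence genes the highest in the spt16-labelled library, 1.404.

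The list of H2A.Z and its exchange complexes had medians near the median gene, 0.02 (percentile 64.0; 2 of 12 members higher, 2 lower) in the spt16-labelled library and -0.09 (percentile 33.1; none higher, 3 lower) in ssrp1, or 0.32 and 0.08 (percentiles 88.9 and 73.8) with elongating reads alone. The H2A.Z gene HTA9 (AT1G52740) had log2 ratios of -0.57 (-0.97 to -0.20) and -0.63 (-1.03 to -0.25), and SWC4 (AT2G47210) of -0.62 and -0.89. PIE1 (AT3G12810), the motor subunit of the exchange complex, was 1.61-fold higher (1.24 to 2.09) in the spt16-labelled library and 1.23-fold (0.927 to 1.63) in ssrp1, and SWC6 (AT5G37055) stood at 1.14-fold (0.781 to 1.65) in the former and was 1.84-fold lower (1.17 to 3.08) in the latter. Transcript elongation factor genes had medians of -0.01 and 0.09 (percentiles 44.5 and 68.3; of 15 members 2 higher and 1 lower, then 4 higher and 1 lower), or 0.03 and 0.36 (percentiles 47.8 and 94.3) with elongating reads. SPT4-1 (AT5G08565) had a log2 ratio of -1.52 (-2.66 to -0.61) in the spt16-labelled library and -0.62 (-1.45 to 0.13) in ssrp1, IWS1 (AT1G32130) 0.56 and 0.81, the polymerase II subunit gene NRPB2 (AT4G21710) 0.46 and 0.52, and VIP5 (AT1G61040) -0.06 and -0.68. The FACT genes as a pair had medians of -0.07 (percentile 44.8) and 0.66 (percentile 97.8), the latter 0.40 (percentile 89.3) with elongating reads.

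Core histone genes lay below the median gene in both libraries, with medians of -0.27 (percentile 0.12; 9 of 26 lower, none higher) and -0.19 (percentile 1.18; 9 of 26 lower, 1 higher), while scaling to nuclear reads alone, which shifts every gene alike and leaves these percentiles as they are, gave -0.05 and 0.05. In ssrp1 the list lay inside the central 95% of random lists with polyadenylated reads alone (percentile 4.70) and with elongating reads alone (-0.15, percentile 12.9), while elongating reads gave -0.50 (percentile 0.16) in the spt16-labelled library. HTR13 (AT5G10390) had log2 ratios of -1.53 and -2.22, HTA6 (AT5G59870) -1.05 and -1.03, H4-5 (AT3G46320) -1.49 and -0.73, and HTA12 (AT5G02560) -1.37 (-3.53 to 0.12) and -0.84 (-2.55 to 0.49). Histone genes and LHCB1 genes are near-identical copies, and the split of reads among members is uncertain. Nuclear photosynthesis genes had a median of 0.31 (percentile 99.3; 22 of 33 higher, 5 lower) in the spt16-labelled library, against 0.03 (percentile 14.7) with elongating reads alone, and of -0.09 (percentile 12.8; 8 higher, 15 lower) in ssrp1, there 0.01 (percentile 48.2) with elongating reads. LHCB1.1 (AT1G29920) had log2 ratios of 1.19 and 0.61, PSBO2 (AT3G50820) 0.66 and 0.53, RBCS1A (AT1G67090) -0.32 and -0.73, and LHCB1.4 (AT2G34430) -0.16 and -0.67.

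Flowering-time regulators had medians of 0.15 (percentile 77.2; 2 of 7 higher, 2 lower) and -0.39 (percentile 1.60; 2 of 7 higher, 3 lower). Polyadenylated reads alone turned both calls, with 0.43 (percentile 98.7, outside the central 95%) and -0.30 (percentile 13.0, inside it), and with elongating reads ssrp1 also lay inside (-0.39, percentile 3.49). FLC (AT5G10140), the main floral repressor, had 2, 3 and 2 reads in wild type, the spt16-labelled library and ssrp1, too few to compare. FT (AT1G65480), the floral activator, had log2 ratios of -1.13 (-2.19 to -0.25) and -0.40 (-1.22 to 0.35), MAF2 (AT5G65050) -0.21 and -0.73, MAF3 (AT5G65060) 0.64 and -0.39, SOC1 (AT2G45660) 0.20 and 0.54, FLM (AT1G77080) -0.20 and -0.52, SVP (AT2G22540) 0.31 and 0.25 and FRI (AT4G00650) 0.15 and 0.20.

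Heat-shock genes (5 measured) had medians of -0.39 and 0.37 (percentiles 13.7 and 93.4; 2 and 1 members lower, none higher), with polyadenylated reads alone putting ssrp1 at percentile 41.8 and with MBF1C (AT3G24500) at -1.47 (-2.47 to -0.66) and 0.41 (-0.15 to 0.96) and HSFA7A (AT3G51910) at -1.31 and -0.99. DNA damage response genes (3 measured) had medians of -0.74 and -0.50 (percentiles 2.33 and 6.72; 1 member lower in each), but -0.20 and -0.21 (percentiles 26.9 and 22.7) with a minimum of 20 reads, and XRI1 (AT5G48720) stood at -0.79 in both. Anthocyanin and flavonoid genes had medians of 0.10 (percentile 69.9, 3 measured) and 0.25 (percentile 82.4, 4 measured). With a minimum of 20 reads the latter was 0.48 (percentile 98.6), outside the central 95%, and with elongating reads the medians were -0.10 and 0.01 (percentiles 32.0 and 46.8). Root markers had medians of -0.08 and 0.03 (percentiles 29.7 and 53.6; 2 of 8 higher and 2 lower, then 3 of 7 lower), or 0.62 and -0.09 (percentiles 91.2 and 35.5) with elongating reads. Dividing cell markers had medians of -0.15 and -0.21 (percentiles 38.3 and 27.1). Cytosolic ribosomal protein genes had -0.23 and -0.04 (percentiles 5.55 and 35.5; none of 7 and then 3 of 7 lower). That list held only 7 genes, taken by name, and may not stand for the whole class.

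The log2 ratios of the spt16-labelled and ssrp1 libraries correlated across 14819 protein-coding genes with at least 50 reads over the 3 libraries together, which are not independent replicates, with a Pearson r of 0.61 and a Spearman rho of 0.59. Both share 1 control library, and unchanged simulated libraries gave 0.36 and 0.34. The covariance was 0.18 against 0.03 in the simulation. When wild type reads were split at random between the comparisons r was 0.45, which separates counting error but not differences of the wild type plants or library, so part of the excess may come from the shared control. Of the genes beyond 2-fold relative to the median gene, 24 were lower in both (0.18 would overlap in independent lists of 35 and 67 genes) and 8 were higher in both (0.45 in lists of 193 and 30). None was called in opposite directions. The unchanged simulated libraries, which share their control, gave 0 such genes in either direction. That value leaves out real effects and differences of the wild type library, and that of independent lists leaves out the shared control, so part of this overlap may also come from the shared control. Compared directly, 130 of 12040 genes were higher in the spt16-labelled library than in ssrp1 and 11 lower beyond 2-fold.

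**Figure D3:**
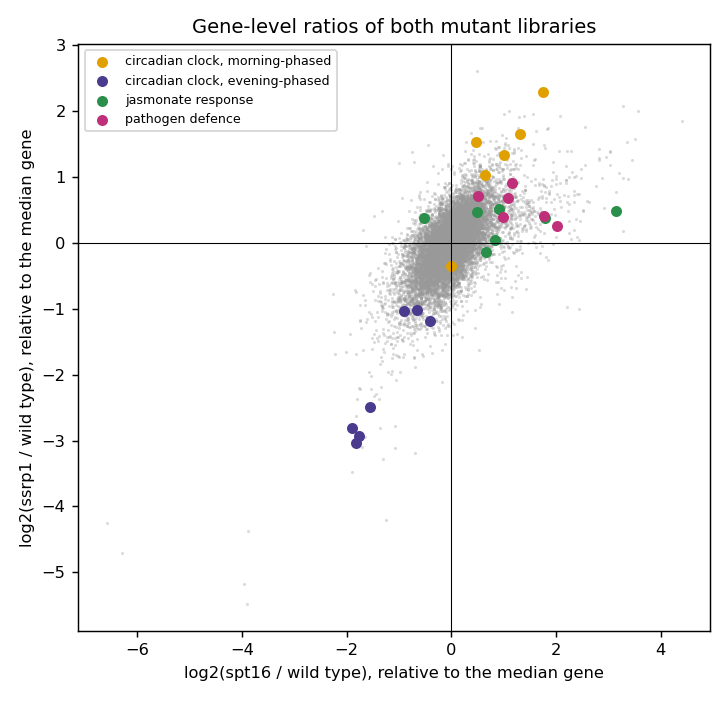
Each grey point is 1 protein-coding gene with at least 50 reads in both comparisons, with its log2 ratio to wild type in the spt16-labelled library (x) and in ssrp1 (y), relative to the median gene; coloured points are morning-phased (yellow) and evening-phased (purple) clock genes, jasmonate (green) and pathogen defence genes (pink). Evening-phased clock genes lie low on both axes, while pathogen defence and jasmonate genes spread along the x axis.

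Genes whose reads pile up at single positions held 33.3% of nuclear gene reads in wild type, 19.5% in the spt16-labelled library and 22.3% in ssrp1. The main one lay inside the RR3 model (AT2G41310, chromosome 2, plus strand), with the most frequent read start at 17224510 and the most frequent end at 17224815, and took 12.6%, 7.41% and 8.20% of nuclear reads. The long non-coding RNA gene AT1G05163 (chromosome 1, 5297847 to 5298571, minus strand) took 6.37%, 2.19% and 3.08%. Polyadenylated reads made up 29.1% of nuclear reads in wild type, 37.5% in the spt16-labelled library and 32.4% in ssrp1. Without the genes with stacked reads, a setting chosen after seeing the data, the shares were 41.2%, 44.1% and 39.5%, so the spt16 difference went from 8.44 to 2.91 percentage points and the ssrp1 difference turned from 3.33 to -1.63. The differences were 2.52 and -1.50 without the 50 most abundant genes, 3.91 and -0.748 as the mean over genes, 5.49 in the spt16-labelled library with organellar genes and 1.67 in ssrp1 with protein-coding genes only. Per gene, the share was higher than in wild type in 8498 of 12721 genes and lower in 4172 for the spt16-labelled library, and higher in 5844 and lower in 6827 for ssrp1. The median tail was 98.9 nt in wild type, 97.3 nt in the spt16-labelled library and 102 nt in ssrp1, differences of -1.53 nt (-1.85 to -1.19) and 3.41 nt (3.08 to 3.72). Per-gene medians gave -2.45 and 1.07 nt, and tails from 10 nt gave -0.78 nt in the spt16-labelled library.

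Splicing in elongating reads differed from wild type in the same direction in the spt16-labelled library and in ssrp1. Of the introns that such reads fully spanned, 55.2% were unspliced in wild type, 51.5% in the spt16-labelled library and 51.2% in ssrp1, differences of -3.69 and -3.99 percentage points. Several introns of 1 read are not independent observations. If those of 1 read always shared their state, the intervals were -4.02 to -3.35 and -4.32 to -3.66. The differences shrank to -0.556 and -2.23 points at least 500 nt from the intron, to -2.28 in the spt16-labelled library without stacked genes and to -2.47 in ssrp1 as the mean over genes. CGL1 (AT4G38240) went from 71.1% (81 of 114) in wild type to 15.8% (26 of 165) in the spt16-labelled library, and SGR2 (AT1G31480) from 70.9% (61 of 86) to 16.2% (17 of 105) in ssrp1. Other genes moved up: CBL1 (AT4G17615) went from 29.4% to 74.3% and BGLU46 (AT1G61820) from 30.2% to 77.3% in the spt16-labelled library, and AT4G39280 from 46.8% to 96.0% in ssrp1. With each intron as 1 observation, 410 of 3484 genes were higher and 898 lower in the spt16-labelled library, and 409 of 3549 higher and 738 lower in ssrp1. With the introns of 1 read as 1 observation, a setting chosen after seeing the data, these fell to 76 and 182, and to 52 and 135. The intervals allow up to 87.1 and 88.7 genes per direction if none differed, and the genes moving up did not exceed that. This strict setting takes the widest case for the intervals, so it does not show that no gene moved up. Within 100 to 200 nt of the intron end, where the gap was widest, the unspliced share was 74.2% in wild type against 66.5% and 66.7%. It was 69.9% against 65.6% and 65.0% at 0 to 100 nt, and 63.1% against 59.7% and 59.4% at 200 to 300 nt. Shares by distance were not computed without genes with stacked reads. At 1000 to 2000 nt the unspliced share was 35.5%, 37.4% and 33.1%, so the spt16 difference changed sign with distance. In polyadenylated reads the differences were 0.15 and 0.44 points, in the opposite direction.

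**Figure D4:**
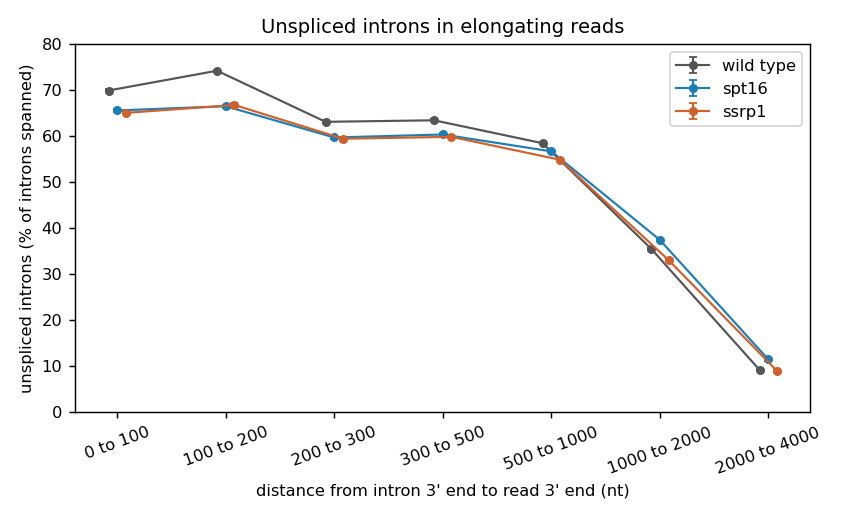
Share of spanned introns that were unspliced in elongating reads, in percent, by the distance in nt from the intron 3′ end to the read 3′ end; points are pooled introns of 1 library and bars are 95% binomial intervals that count each intron as 1 observation. Wild type lies above the 2 other libraries up to 1000 nt, with the widest gap at 100 to 200 nt (74.2% against 66.5% and 66.7%). Genes with stacked reads are included.

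More elongating reads ended past the annotated gene end in the spt16-labelled library and in ssrp1. In protein-coding genes of at least 1000 nt the share was 5.46% in wild type, 8.41% in the spt16-labelled library and 7.71% in ssrp1, differences of 2.94 (2.86 to 3.02) and 2.24 (2.17 to 2.32) percentage points, the latter 1.34 without stacked genes and 1.38 for ends more than 100 nt past. ATI1 (AT2G45980) had 15.1% of 93 reads past its end in wild type and 43.5% of 62 in the spt16-labelled library. ELP (AT1G12090) went from 5.51% of 254 reads to 24.4% of 78 there and 20.4% of 93 in ssrp1, and AT1G21000 from 4.39% of 114 to 21.0% of 100 in ssrp1. AT1G56700 went the other way in ssrp1, from 20.0% of 65 to 0 of 56, which allows up to 5.36% (3 of 56). Beyond counting error, 250 of 1953 genes were higher and 14 lower in the spt16-labelled library, and 139 of 2240 higher and 27 lower in ssrp1, where 48.8 and 56.0 per direction would be allowed if none differed. The share of 3′ ends in the first 300 nt was 2.79%, 2.71% and 2.87%, differences of -0.08 and 0.08 points, but in all 4 alternatives it was lower in both, as without stacked genes at -1.01 and -0.78 points. AT2G30020 went from 37.5% to 6.04% in the spt16-labelled library, and the calmodulin-like gene TCH3 (AT2G41100) from 26.1% to 11.9% in ssrp1.

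Polyadenylated reads more often began inside genes in the spt16-labelled library and in ssrp1. The share with a 5′ end at least 200 nt inside the annotated gene was 58.8% in wild type, 62.1% in the spt16-labelled library and 68.3% in ssrp1, differences of 3.30 (3.14 to 3.46) and 9.51 (9.35 to 9.67) percentage points. LTPG2 (AT3G43720), a lipid transfer protein gene, went from 40.8% (75 of 184) to 79.3% (65 of 82) in ssrp1, and AT4G21660 from 52.2% to 90.2%. PSRP4 (AT2G38140) went from 17.1% (31 of 181) to 48.1% (37 of 77) in the spt16-labelled library, and AK3 (AT3G02020) from 51.4% to 82.0%. In ssrp1, 742 of 2447 genes were higher beyond counting error and 7 lower, and in the spt16-labelled library 225 of 2829 higher and 53 lower, where 61.2 and 70.7 per direction would be allowed if none differed. The median length of polyadenylated reads was 916 nt in wild type, 921 nt in the spt16-labelled library and 835 nt in ssrp1. Chloroplast reads also began at least 200 nt inside their genes more often, at 45.1%, 51.0% and 54.6%, and mitochondrial reads did so at 50.2%, 48.4% and 53.3%. The organellar shares were taken over reads with or without a tail.

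**Figure D5:**
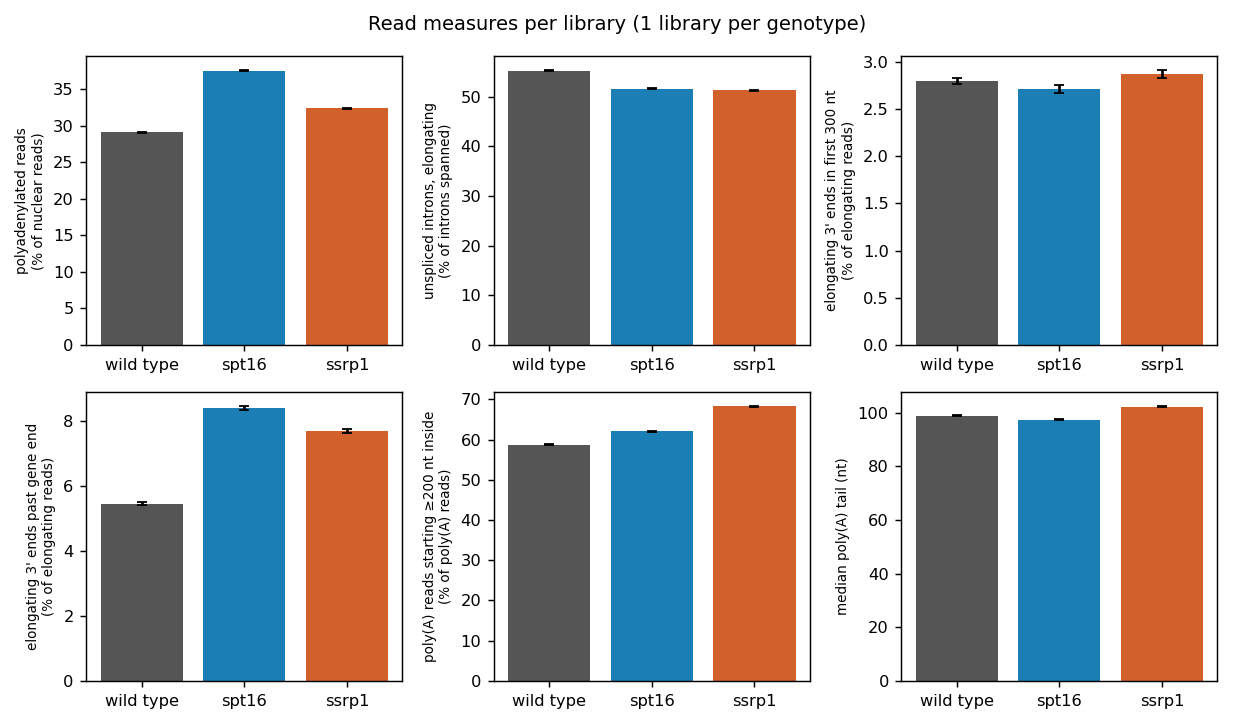
Bars give 6 read measures for the 3 libraries, in percent or nt as labelled, with 95% intervals that cover counting error only. Shares of elongating 3′ ends past the gene end (5.46%, 8.41% and 7.71%) and of polyadenylated reads starting inside genes (58.8%, 62.1% and 68.3%) are higher in the spt16-labelled and ssrp1 libraries than in wild type.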

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

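The tests on organellar reads, on genes with stacked reads and on the clock lists were chosen only after the result was seen, while those on fixed 5′ end positions and on poly(A) sites were set before their result was seen. No difference between the spt16-labelled and ssrp1 libraries in the results that went in opposite directions was tested.

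Polyadenylated reads began inside genes more often in the spt16-labelled and ssrp1 libraries than in wild type. Fixed start sites inside genes were tested by the share of internal 5′ ends in the fullest 20 nt window of a gene, whose median difference was 0 percentage points in the spt16-labelled library (1485 genes) and -0.45 in ssrp1 (1422 genes, interval -1.06 to 0). The limit of 1 point set for this test was wrong, because the extra internal reads made up only 5.32% and 13.9% of internal reads while the fullest window already held 10.6% and 10.4% of them in wild type, so sites spread over several positions need not raise it. Shorter RNA or cDNA molecules may account for some or all of the ssrp1 difference. Chloroplast and mitochondrial reads also began inside their genes more often there, by 9.47 and 3.09 points. These organellar reads were of all classes, with or without a tail, while the nuclear share held only polyadenylated reads of protein-coding genes. The read sets differ, so the organellar shares cannot single out shorter molecules. In the spt16-labelled library the organellar genomes moved apart, by 5.95 points (5.73 to 6.17) for chloroplast and -1.77 points for mitochondrial reads. Shorter molecules and a genotype effect therefore cannot be told apart there.

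Elongating reads ended past the annotated gene end more often in the spt16-labelled and ssrp1 libraries than in wild type. Stacked reads inside gene models, more frequent in wild type, could lower its share, but without those genes the differences were still 2.12 (2.01 to 2.23) and 1.34 (1.23 to 1.44) percentage points, so they are not the whole cause. Poly(A) sites moved downstream would carry polyadenylated reads along. Of these, 1.16% ended more than 100 nt past the gene end in wild type, 1.27% in the spt16-labelled library and 1.26% in ssrp1. The differences were 0.106 (0.070 to 0.142) and 0.0985 (0.061 to 0.137) points. Elongating reads differed by 2.02 and 1.38 points at that distance. This argues against moved poly(A) sites as the whole cause beyond 100 nt, while shorter shifts were not tested. An effect of the genotypes stays open and untested, with 1 library each.

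The morning-phased clock list lay above matched random lists and the evening-phased list below them in the spt16-labelled and ssrp1 libraries, although only 4 of 6 morning genes were higher in the former and 1 of 7 was lower in the latter. With elongating reads alone the morning list of the spt16-labelled library lay inside the central 95% (0.55, percentile 95.9), and the lists stood 1.52 and 2.91 apart on the log2 scale. With all reads the list medians lay 2.38 apart in the spt16-labelled library and 4.03 apart in ssrp1, which is consistent with a harvest at another time of day than wild type. An effect of the genotype on the clock would also separate the lists, and the observed 2.38 and 4.03 meet that too. Both criteria were written after this pattern was seen, so meeting them adds no evidence. With 1 library per genotype and no recorded harvest time the explanations cannot be told apart.

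The share of elongating 3′ ends in the first 300 nt went in opposite directions, -0.082 percentage points in the spt16-labelled library and 0.079 in ssrp1 against wild type. The direction in ssrp1 did not hold, since it turned negative in all 4 alternatives run (-0.550 to -0.782). The median poly(A) tail went in opposite directions too, at -1.53 nt and 3.41 nt, but at 1.07 nt in ssrp1 with per-gene medians and -0.78 nt in the spt16-labelled library with tails from 10 nt. Some groups of reads that no comparison above set apart exceeded the wild type level as a share of all or of nuclear reads. Those totals hold the genes with stacked reads, which took 33.3% of nuclear reads in wild type, 19.5% in the spt16-labelled library and 22.3% in ssrp1. That lowers other shares most in wild type. Stacked reads, all of nuclear genes, numbered 1036172, 345223 and 391826. With these taken off the totals of all reads, the mitochondrial share would be lower in ssrp1 than in wild type. The chloroplast share would stay higher in the spt16-labelled library and lie only slightly above wild type in ssrp1. The shares of nuclear reads below were not computed without these genes, so the direction of those small differences is uncertain. Chloroplast genes took 17.04% of all reads in the spt16-labelled library and 13.9% in ssrp1, against 12.0% in wild type, and mitochondrial genes 0.987% in ssrp1 against 0.943%. Splicing intermediates made up 10.4% and 10.7% of nuclear reads against 9.78%. Polyadenylated reads ending outside the last exon made up 0.849% in the spt16-labelled library and 0.748% in ssrp1, against 0.765% in wild type.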

How the results depend on the processing

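Leaving out genes with stacked reads, keeping protein-coding genes only, counting introns that hold the read start, leaving out reads listed more than once, introns of 1 read as 1 observation, and elongating reads for gene lists were chosen after seeing the data. All other alternatives were set before the data were examined. Antisense reads were not analysed here. No paired analysis was possible because each genotype had 1 library. Values are differences from wild type, for the spt16-labelled library and then ssrp1, and the cause of a change was not tested except where a setting tests fewer genes or reads. The polyadenylated share of the spt16-labelled library, and 3′ ends past the gene end and internal starts of both other libraries, kept their sign under every alternative run. Each main measure or count gave 1 value per alternative. Under planned settings 17 of these values stayed within their error or 1.5 times, 41 moved and 7 reversed. Under added settings 5 stayed, 15 moved and 2 reversed. For listed genes this compares their number only, and the genes themselves could change. With elongating reads alone 90 genes were higher in ssrp1 against 95, but only 45 were in both lists. With polyadenylated reads alone 19 were lower in the spt16-labelled library against 21, with 9 in both. Thinning kept more, with 291 of 300 higher genes of that library in the main list. For gene lists, median ratios and gene counts of splicing 50 and 8 stayed, 12 and 22 moved, and 1 and 1 reversed. A further 32 list values could not move because they are relative to the median gene already.

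With the mean or median over genes, the polyadenylated share differed by 3.91 and -0.748 points, the latter reversed. Unspliced introns differed by -2.47 points in ssrp1, 3′ ends in the first 300 nt by -1.04 and -0.652 (the latter reversed), 3′ ends past the gene end by 3.08 and 1.51, internal starts by 2.52 and 7.90, and tails by -2.45 nt and 1.07 nt. Without genes with stacked reads the polyadenylated share differed by 2.91 and -1.63 (the latter reversed), unspliced introns by -2.28 and -2.96, first 300 nt ends by -1.01 and -0.782 (the latter reversed), ends past the gene by 2.12 and 1.34, and internal starts by 3.50 in the spt16-labelled library. The same setting gave 225 genes higher and 33 lower in the spt16-labelled library, 43 higher and 64 lower in ssrp1, and a reversed median log2 ratio of -0.0398 in the former.

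The polyadenylated share differed by 5.49 and 2.26 points with organellar genes, 8.77 and 3.55 with tails from 10 nt, 7.995 and 3.15 with tails from 20 nt, 2.52 and -1.50 (the latter reversed) without the 50 most abundant genes, and 6.28 and 1.67 in protein-coding genes. Tails from 10 nt put the median tail at -0.78 nt in the spt16-labelled library. Unspliced introns reversed to 0.148 and 0.436 in polyadenylated reads, differed by -0.556 and -2.23 at least 500 nt from the intron, and by -3.93 and -3.27 with introns that hold the read start. Ends in the first 500 nt differed by -0.755 and -0.673 and, in genes of 1000 to 3000 nt, first 300 nt ends by -0.867 and -0.550, with ssrp1 reversed in both. Ends more than 100 nt past the gene differed by 2.02 and 1.38, and ends past genes of 1000 to 3000 nt by 2.60 and 1.89. Starts at least 500 nt inside differed by 10.7 in ssrp1.

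Polyadenylated reads alone gave 85 and 13 genes higher, with a reversed median log2 ratio of -0.00119 in the spt16-labelled library. Elongating reads alone gave 394 and 90 higher, and 5 and 9 lower. Centring on the median gene gave 36 lower in the spt16-labelled library, and 40 higher and 67 lower in ssrp1. A minimum of 200 reads, which tests fewer genes, gave 218 higher and 11 lower, and 38 higher and 18 lower. Thinning to the shallowest library, which leaves fewer reads, gave 13 lower in the spt16-labelled library. The correlation of both ratios was 0.45 with wild type reads split, 0.64 with at least 200 reads and 0.59 with polyadenylated reads.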

Other observations

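Other loci with stacked reads went both ways in their share of nuclear reads. AT2G35750 (chromosome 2, 15029829 to 15030290, minus strand) took 1.98% in wild type, 0.851% in the spt16-labelled library and 0.932% in ssrp1, and the snoRNA gene AT2G04965 took 1.21%, 0.538% and 0.553%. AT1G09915 took 1.31%, 1.08% and 1.09%. Higher than in wild type were the snoRNA gene AT4G39363 (0.218%, 0.334% and 0.390%), LHCB3 (AT5G54270; 0.154%, 0.253% and 0.199%) and LHCB1.1 (AT1G29920; 0.0816%, 0.219% and 0.148%).

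Single members of the root list went different ways. PRP3 (AT3G62680) was 4.11-fold higher in ssrp1 (2.07 to 9.32; 31 against 11 reads) and stood at 1.24-fold (0.450 to 3.26) in the spt16-labelled library. TIP2;3 (AT5G47450), an aquaporin gene, was 2.15-fold lower (1.26 to 4.03) in the spt16-labelled library and 3.01-fold lower (1.65 to 6.38) in ssrp1. DL1C (AT1G14830), a dynamin-related gene, had no elongating read past its end among 63 in wild type, which allows up to 4.76%, against 13 of 52 in the spt16-labelled library and 1.89% of 53 in ssrp1.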
